A study of Mus musculus with 3 samples.

How the data were processed

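Total RNA was isolated with TRIZOL and RNeasy from pulverized femora, tibiae and humeri, per the labels' protocols, and aminoallyl cDNA was coupled to Cy3 or Cy5. The labels name the tissue of these samples as bone marrow. Each of 3 arrays compared the bone marrow of 1 castrated mouse given testosterone with that of its matched placebo mouse. The pellets held 12.5 mg and released over 60 days, and treatment lasted 4 weeks. The series title also speaks of bone, whose arrays were not analysed here. The 3 arrays form 1 group of 3 mouse pairs, and each value is a ratio within a pair.

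The deposited values are signed log ratios, 1 per spot and array, which are read here as log2. The base is inferred: the range of the values (lowest -3.37, highest 4.47) makes base 10 implausible, and a natural log is not excluded, in which case every fold given here would be larger. Numerator, direction and scaling are not stated in the sources used here. The authors name testosterone as the experimental and placebo as the control channel, per the series' design text, so positive was read as higher with testosterone. The rule for T2, the array of opposite dyes, was to keep its deposited sign unless it correlated below -0.1 with both other arrays while these correlated above 0.1. All correlations were positive, so no sign was turned. If T2 were in truth a ratio of Cy5 to Cy3, turning it would exchange treatment and dye effect, so this orientation was run as an alternative. The scanner, background correction and filter are not given in the sources used here. Every one of 32 consecutive runs of 361 spots had a mean near 0 on each array, the largest being 0.0054 on T1, 0.012 on T2 and 0.054 on T3, the pattern left by normalization within print blocks. The column medians were 0.007, -0.062 and -0.025, and the standard deviations 0.303, 0.497 and 0.332. The values were used as deposited, with no further normalization, so changes are relative to the average spot of each block.

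The number of arrays limits the precision: the median standard error of a spot was 0.118, so that a 95% interval reaches 0.269 to either side on the log2 scale. Spot brightness was not analysed here, so no spot could be judged against its background. Values were present for 78.0% of spots on T1, 58.6% on T2 and 60.4% on T3, and 1990 spots had a value on T1 only.

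The platform annotation listed 1 gene for 8050 spots, several for 672 and none for 2830, and genes were named only from spots with 1 gene. Symbols were updated through Entrez IDs and the RefSeq gene table of assembly GRCm38.p6, which matched 7880 spots to 5707 genes. No coordinates are given, because no genome build belongs to these values. Control or non-mouse spots, recognised by a symbol in capitals whose Entrez ID was not in the mouse table, numbered 66, and the 12 of them with values on all arrays were left out of the tests. This last choice was made after the data were seen.

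Spots with a value on all 3 arrays were tested against a log ratio of 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. For gene level values, 854 genes with more than 1 spot were averaged per array. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 on these gene level ratios, adjusted over the 22 lists with at least 5 measured genes. The cell type lists were erythroid, B lineage, neutrophil, monocyte and macrophage, megakaryocyte and platelet, osteoblast and matrix, osteoclast, adipocyte, endothelial, marrow stroma and skeletal muscle. The pathway lists were androgen response, sex steroid signalling, cell cycle, ribosomal proteins, oxidative phosphorylation, proteasome, glycolysis, heme synthesis and iron, interferon response, early response and heat shock, and bone growth factors and cytokines. A further 5 lists fell below 5 measured genes and were not tested. An estimated correlation and the directional and mixed tests of fry served as alternatives. With a preset correlation 9 lists passed, 5 lower and 4 higher, with an estimated correlation 0, and with directional fry 0. Mixed fry called 2 lists, B lineage (adjusted p = 0.0425) and monocyte and macrophage (adjusted p = 0.0461).

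The genes named are the 12 most positive and the 12 most negative spots with 1 gene name that passed with the same sign on all arrays. To these were added the 4 genes of smallest p in each list that passed, the 2 of smallest p in each other list, and 10 genes always named where measured, of which 3 were (Col1a1, Esr1 and Igf1). The orientation rule, tests, lists, naming rule and alternatives were fixed before the data were examined, except where stated. The alternatives were the sign of each array turned, each array left out in turn, a dye term, median centring, centring with scaling, spots with a value on at least 2 arrays, robust eBayes, a threshold of 0.10 and 1 value per gene.

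The procedure was tested on simulated data for the comparison of testosterone with placebo. In 20 runs over 6039 spots with 200 changed spots each, 30.0% of changes of 0.5, 97.6% of changes of 1 and 99.9% of changes of 2 on the log2 scale were recovered, and 4.72% of the called spots were false. Over 3462 genes, a list shifted by 0.5 was called in 100% of runs and 0.238% of unchanged lists were called. The simulation drew genes independently, which real lists are not. It also gave the 3 arrays equal spread and no dye effect. Over the tested spots the standard deviation was 0.316 on T1, 0.491 on T2 and 0.324 on T3. The simulated share of false spots therefore need not hold for these arrays.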

Results

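Bone marrow RNA of castrated C57BL/6 mice that received testosterone pellets was compared with that of matched placebo mice on 3 two-colour spotted arrays, named T1, T2 and T3. Each array held 1 pair of mice (n = 3 pairs), and testosterone was labelled with Cy5 on T1 and T3 and with Cy3 on T2. The mice were castrated at 7 weeks of age, were treated for 4 weeks and were 17 weeks old at collection. Of 11552 spots, 9007 had a value on T1, 6771 on T2 and 6982 on T3, and 6039 with a value on all 3 arrays were tested. These tested spots included 4554 with a single named gene, for 3462 genes. Values are read as log2 ratios of testosterone to placebo. The direction is likely and not settled, because it rests on the study's naming of testosterone as the experimental channel, and the log base was inferred from the range of the values.

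Of 15 measured markers of the B lymphocyte lineage, 7 were lower with testosterone than with placebo, on all 3 arrays, 0 were higher and 8 did not pass. The list lay lower than the other genes by camera (adjusted p = 8.35e-06, and adjusted p = 0.80 with an estimated correlation). Vpreb3, which is expressed in B-cell precursors and binds immunoglobulin chains, fell by 2.98 ± 0.66 on the log2 scale (mean ± SD, n = 3; 7.86-fold lower; adjusted p = 0.000268). Bach2, a transcriptional repressor in B cells, was lower at both of its spots, by 5.78-fold (log2 ratio -2.53 ± 0.18, adjusted p = 5.74e-05) and 5.29-fold (-2.40 ± 0.40, adjusted p = 0.000155). Cd79b, a signalling chain of the B-cell receptor, was 4.32-fold lower (-2.11 ± 0.14, adjusted p = 6.91e-05), and Pou2af1, a B-cell coactivator of octamer-binding transcription factors, was 4.19-fold lower (-2.07 ± 0.41, adjusted p = 0.000348). Among named spots that passed as higher, the largest mean was that of Bdp1, a subunit of the initiation factor of RNA polymerase III (2.77-fold, 1.47 ± 0.98, adjusted p = 0.0443), which was 0.39 with the sign of T2 turned and 1.02 without T3, below Stxbp6, Nlgn1 and Hsd3b2.

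In total, 171 of 6039 spots (2.83%) differed from 0 by limma after Benjamini-Hochberg adjustment, 68 higher and 103 lower with testosterone. All 171 had the same sign on the 3 arrays, which the test itself favours, since mixed signs lower the mean and widen the spread. Of these, 17 were at least 2-fold higher and 41 at least 2-fold lower. The lower spots with a single named gene numbered 88, for 80 genes, and the higher ones 25, for 24 genes. The share of higher spots among the changed spots was 39.8% on the values as deposited, 7.02% (4 of 57) after centring each array on its median, and 72.9% (595 of 816) after centring and scaling the arrays to the same spread. With the sign of T2 turned, which exchanges the treatment with a dye effect, 0 spots passed by limma and 20 had an unadjusted p under 0.05, against 1808 with the sign as deposited. Leaving out T1 gave 1095 changed spots (682 higher, 413 lower), leaving out T2 gave 84 (21 higher, 63 lower) and leaving out T3 gave 38, all of them lower.

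Among the lower spots outside the B-lineage markers fixed for this comparison, Fcrla, an Fc receptor-like protein of B cells, fell by 2.51 ± 0.22 (5.71-fold, adjusted p = 5.74e-05, n = 3). Pafah1b3, a catalytic subunit of platelet-activating factor acetylhydrolase, was 3.58-fold lower (-1.84 ± 0.36, adjusted p = 0.000407). Sox4, a transcription factor required in B-cell progenitors, was 3.53-fold lower (-1.82 ± 0.44, adjusted p = 0.000884). Cecr2, a bromodomain protein of chromatin remodelling complexes, was 3.37-fold lower (-1.75 ± 0.56, adjusted p = 0.00281), and the kinase Sbk1 was 3.32-fold lower (-1.73 ± 0.40, adjusted p = 0.000884). Igfbp5, a secreted binding protein of insulin-like growth factors, was 3.19-fold lower at its lowest spot (-1.67 ± 0.52, adjusted p = 0.00281). Each of the 12 most negative named spots, which these and the B-lineage spots above and Il7r make up, kept its direction and its call when any single array was left out. With T2 turned none of them passed, and their means ran from -0.80 (Pafah1b3) to -0.18 (Igfbp5), with Vpreb3 at -0.73, Bach2 at -0.74 and -0.49, and Il7r at -0.28.

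Among the 12 most positive named spots, which Bdp1 leads, Stxbp6, a syntaxin-binding protein, was 2.54-fold higher (1.34 ± 0.86, adjusted p = 0.0423, n = 3), Hsd3b2, a steroid dehydrogenase, 2.46-fold higher (1.30 ± 0.75, adjusted p = 0.0347) and Nlgn1, a neuronal adhesion protein, 2.40-fold higher (1.26 ± 0.84, adjusted p = 0.0446). Angptl1, a secreted angiopoietin-like protein, was higher at both of its spots (0.996 ± 0.30, 1.99-fold, adjusted p = 0.00875; and 0.70 ± 0.29, 1.63-fold, adjusted p = 0.0403). Grem1, a secreted antagonist of bone morphogenetic proteins, was 1.84-fold higher (0.88 ± 0.38, adjusted p = 0.0268). The other 5 were Cc2d2b (0.81 ± 0.47), the surface protein Ly6g6c (0.70 ± 0.35), the zinc finger protein Zc3h7b (0.67 ± 0.24), the phosphatase Dusp9 (0.64 ± 0.28) and the mitochondrial peptidase subunit Immp1l (0.60 ± 0.15), with adjusted p from 0.039 to 0.0476. Averaged over all spots of the gene, Zc3h7b (0.31, adjusted p = 0.104) and Immp1l (0.22, adjusted p = 0.195) did not pass. None of these 12 spots passed without T3 (adjusted p from 0.162 to 0.261), 7 of them (Bdp1, Grem1, Cc2d2b, the smaller of the Angptl1 spots, Ly6g6c, Dusp9 and Immp1l) did not pass without T2 (0.0816 to 0.145), and of the 12 the larger of the Angptl1 spots alone passed after median centring. Robust eBayes ended the calls of Bdp1 (adjusted p = 0.0678), Stxbp6 (0.0654), Hsd3b2 (0.0604), Nlgn1 (0.0688) and Cc2d2b (0.055). Without T2 the mean of Stxbp6 was 0.87 and that of Nlgn1 0.80, against 1.44 and 1.40 without T3. With T2 turned, the mean was -0.18 for Stxbp6, -0.098 for Hsd3b2, -0.20 for Nlgn1, -0.030 for Cc2d2b and -0.0030 for Ly6g6c.

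**Figure D1:**
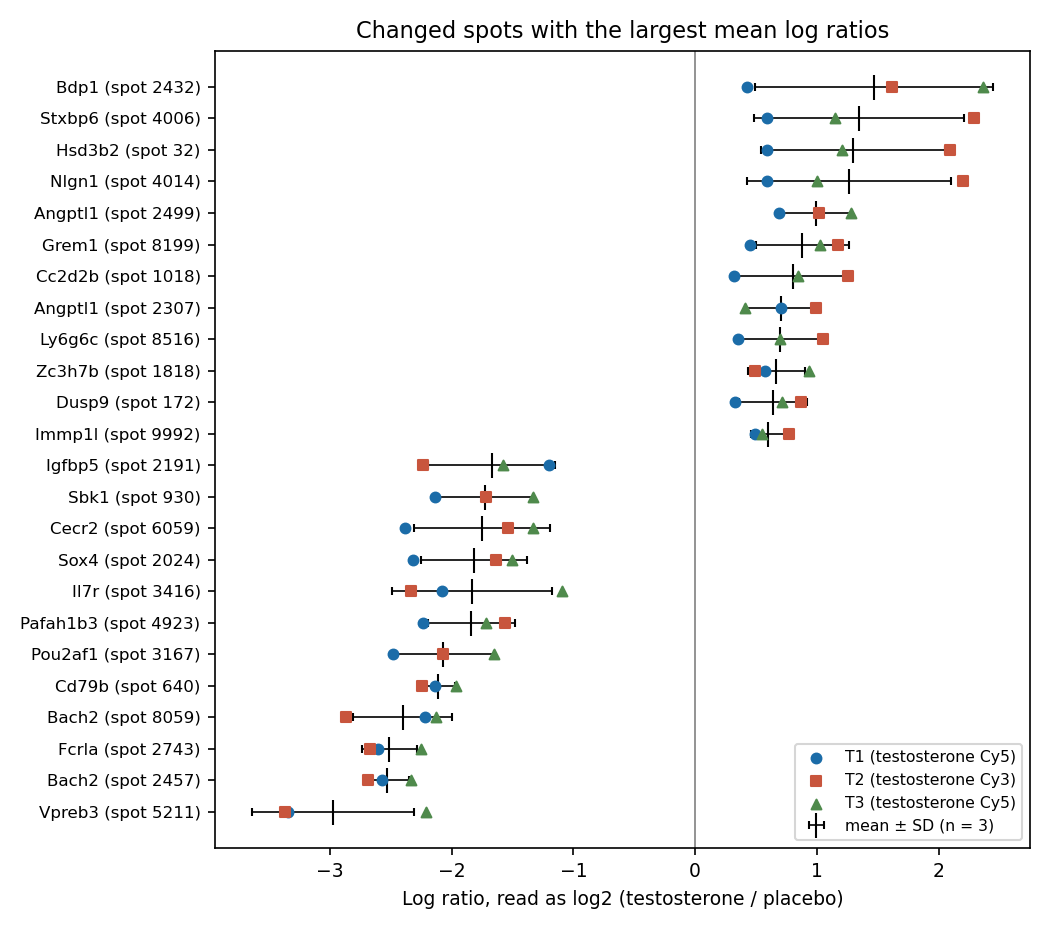
Log2 ratios of testosterone to placebo (horizontal axis) of the 12 most positive and 12 most negative changed spots with a single named gene (vertical axis), with 1 symbol per array and the mean ± SD of the 3 arrays as a line with bars. The lower spots run from Vpreb3 at -2.98 to Igfbp5 at -1.67, and the higher spots from Immp1l at 0.60 to Bdp1 at 1.47.

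The count of 7 lower B-lineage markers among 15 is over all genes tested, and 8 were lower when adjusted over the list alone. At gene level, where the spots of a gene were averaged, the 7 included Blk, a Src-family kinase of B cells (-1.56 ± 0.08, 2.94-fold, adjusted p = 0.000235, n = 3), and Il7r, a subunit of the interleukin-7 receptor that B-cell precursors require in mice, whose single spot was 3.57-fold lower (-1.84 ± 0.66, adjusted p = 0.00365). Over all 15 genes the median was -0.36, with -0.66 on T1, -0.88 on T2 and -0.46 on T3. The list's call held without each single array and was lost with T2 turned (mean -0.21 against -0.97 as deposited, adjusted p = 0.343).

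**Figure D2:**
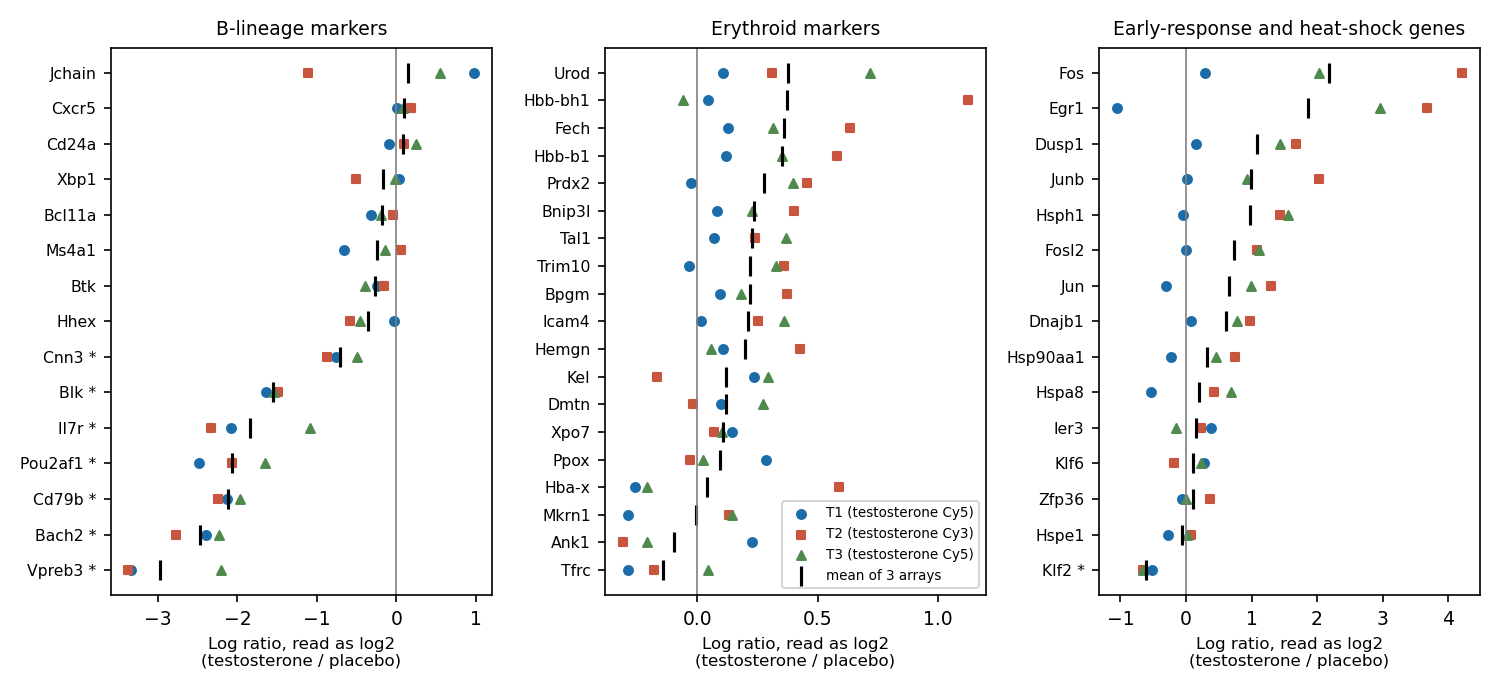
Log2 ratios of testosterone to placebo (horizontal axes) of each measured gene (vertical axes) of the B-lineage, erythroid and early-response lists, with 1 symbol per array, a bar at the mean of the 3 arrays, and a star beside genes that passed over all genes tested. In the B-lineage panel 7 genes carry a star, in the erythroid panel none, and in the early-response panel Klf2, at -0.61.

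The early-response and heat-shock list lay higher (15 genes; median 0.62; adjusted p = 0.000818 by camera, and adjusted p = 0.80 with an estimated correlation), although the only member that passed over all genes tested was lower. That member was Klf2, a transcription factor of lymphocyte quiescence and trafficking (-0.61 ± 0.07, 1.53-fold lower, adjusted p = 0.0199, n = 3; adjusted p = 0.131 without T2 and 0.243 without T3). When adjusted over the list alone, 6 members were higher and 1 was lower. The immediate-early factor Fos had a ratio of 2.18 ± 1.97 (adjusted p = 0.0679), the phosphatase Dusp1 1.09 ± 0.82 (adjusted p = 0.053) and the chaperone Dnajb1 0.62 ± 0.48 (adjusted p = 0.0703). The list's median was -0.05 on T1, 0.98 on T2 and 0.79 on T3, and the ratios of Fos on these arrays were 0.29, 4.22 and 2.03. The list's mean of 0.62 was 0.99 without T1, 0.35 without T2 and -0.15 with T2 turned.

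Skeletal muscle markers, of a tissue that adjoins the collected bones, lay lower (9 genes; median -0.35; adjusted p = 0.0239 by camera, and adjusted p = 0.816 with an estimated correlation). None passed over all genes tested, and 1, Mylpf, a light chain of fast muscle myosin, was lower when adjusted over the list alone (-0.69 ± 0.52, n = 3). The creatine kinase Ckm had a ratio of -0.72 ± 0.79, the tropomyosin Tpm2 -0.42 ± 0.38 and the enolase Eno3 -0.35 ± 0.39. As for the early-response list, T1 stood apart, with a muscle median of -0.003 on T1, -0.78 on T2 and -0.38 on T3. The list's mean of -0.38 was -0.58 without T1, -0.17 without T2, where the call was lost (adjusted p = 0.166), and 0.15 with T2 turned.

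Erythroid markers lay higher by camera (19 genes; median 0.21; adjusted p = 0.000818, and adjusted p = 0.80 with an estimated correlation), with 16 of 19 gene means above 0 and no member past the threshold over all genes tested or adjusted over the list alone. The beta-globin Hbb-b1 had a ratio of 0.35 ± 0.23, and the antioxidant Prdx2 of red cells had 0.28 ± 0.26 (n = 3). The overlapping list of heme synthesis and iron genes also lay higher (6 genes; median 0.25; adjusted p = 0.0326, and adjusted p = 0.80 with an estimated correlation), again with no member past either threshold. Fech, the ferrochelatase of heme synthesis, stood at 0.36 ± 0.26, the decarboxylase Urod at 0.38 ± 0.31, the ferritin light chain Ftl1 at 0.28 ± 0.20 and the iron-regulatory aconitase Aco1 at 0.21 ± 0.09. Without T2 the mean of Fech was 0.22, and without T3 that of Urod was 0.21. The heme call was lost without T3 (adjusted p = 0.118), with a dye term (0.0594) and with T2 turned (0.356), and the erythroid mean was -0.012 with T2 turned.

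Monocyte and macrophage markers lay higher by camera (7 genes; median 0.12; adjusted p = 0.0377, and adjusted p = 0.80 with an estimated correlation). No member passed over all genes tested or adjusted over the list alone. The efferocytosis receptor Mertk had a ratio of 0.33 ± 0.09, the scavenger receptor Cd163 of 0.33 ± 0.18, Aif1 of 0.25 ± 0.10 and Axl of 0.12 ± 0.10 (n = 3). The call was lost without T1 (mean 0.063 against 0.15, adjusted p = 0.422), with a dye term (0.112) and with T2 turned (0.0576).

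Genes of the proteasome lay lower (30 genes; median -0.19; adjusted p = 0.000991 by camera, and adjusted p = 0.80 with an estimated correlation), and all 30 gene means were below 0. Psmb8, an inducible subunit of the immunoproteasome, was 1.45-fold lower over all genes tested (-0.54 ± 0.13, adjusted p = 0.0409, n = 3), and when adjusted over the list alone Psmb10, another inducible subunit, was lower as well (-0.52 ± 0.24). Psmd8 had -0.32 ± 0.17 and Psmb4 -0.25 ± 0.11. Genes of oxidative phosphorylation lay lower (52 genes; median -0.15; adjusted p = 0.00602, and adjusted p = 0.816 with an estimated correlation), with 49 means below 0, 1 member lower over all genes tested, Cox7a2l (-0.49 ± 0.15, adjusted p = 0.0467), and 0 adjusted over the list alone. Other members included the ATP synthase subunits Atp5a1 (-0.37 ± 0.07) and Atp5g2 (-0.30 ± 0.04) and the complex I subunit Ndufa10 (-0.31 ± 0.18). Ribosomal protein genes lay lower (42 genes; median -0.15; adjusted p = 0.0226, and adjusted p = 0.886 with an estimated correlation) with 0 members past either threshold, examples being Rpl28 (-0.31 ± 0.03), Rpl7 (-0.29 ± 0.09), Rps19 (-0.30 ± 0.15) and Rpl14 (-0.26 ± 0.09). Their median was -0.34 on T1, -0.06 on T2 and -0.04 on T3. With T2 turned the calls of the proteasome (adjusted p = 0.574) and of oxidative phosphorylation (adjusted p = 0.279) were lost, and without T1 the calls of oxidative phosphorylation (adjusted p = 0.237) and ribosomal proteins (mean -0.056 against -0.15, adjusted p = 0.945, and 0.141 with a dye term) were lost. The calls of Psmb8 and Cox7a2l were lost without T2 (adjusted p = 0.213 and 0.227), without T3 (0.273 and 0.243) and after median centring (0.0547 and 0.0629).

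Lists of bone and stromal genes did not pass by camera. Among 18 bone growth factor and cytokine genes (median 0.08; adjusted p = 0.134), Igfbp5 was lower over all genes tested (gene mean -1.57 ± 0.29, 2.96-fold, adjusted p = 0.000682, n = 3), and adjusted over the list alone 4 were higher and 2 lower. The growth hormone receptor Ghr was 1 of the 4 (0.85 ± 0.60, adjusted p = 0.053 over all genes tested). In the list of 13 osteoblast and matrix genes (median -0.18; adjusted p = 0.602), the collagen Col6a1 was 1.76-fold lower (-0.81 ± 0.22, adjusted p = 0.0107), the single member past the threshold over all genes tested and adjusted over the list alone. Sparc, a matrix glycoprotein of bone, had -0.50 ± 0.50, and -0.23 without T2. The collagen Col1a1 had -0.08 ± 1.13, with 1.10 on T1, -1.16 on T2 and -0.16 on T3. The 13 stromal genes (adjusted p = 0.396) had Igfbp5 as the single lower member over all genes tested, and 4 higher and 1 lower adjusted over the list alone, among them the transcription factor Ebf3 (0.46 ± 0.19). Their median was -0.03 and their mean -0.0025, while camera placed the list on the higher side. Of 6 osteoclast genes (median 0.10; adjusted p = 0.152), 0 passed over all genes tested, and the chloride transporter Clcn7 was higher adjusted over the list alone (0.37 ± 0.12), with Mmp14 at 0.14 ± 0.19. The calls of Col6a1 were lost without T2 (adjusted p = 0.107) and without T3 (adjusted p = 0.17).

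Adipocyte markers (7 genes; median -0.30; adjusted p = 0.152) and genes of the androgen response (26 genes; median -0.03; adjusted p = 0.842) did not pass by camera, and Scd1, a stearoyl desaturase that both lists hold, was the single member of either that changed over all genes tested (-1.21 ± 0.41, 2.31-fold lower, adjusted p = 0.0058, n = 3). Its call was lost without T2 (adjusted p = 0.0843). Adjusted over the list alone, 1 adipocyte gene, the amine oxidase Aoc3, was higher (0.41 ± 0.20) and 3 were lower, and 2 androgen response genes were lower, Scd1 and the spermine synthase Sms (-0.41 ± 0.08). Of 6 genes of sex steroid signalling (adjusted p = 0.717) 0 passed over all genes tested or adjusted over the list alone, with Hsd17b10 at -0.19 ± 0.04 and the chaperone Hsp90aa1 at 0.32 ± 0.50. Their median was -0.02, their mean 0.02, and camera placed them on the higher side. The estrogen receptor Esr1 had a ratio of 0.05 ± 0.20 (adjusted p = 0.792) and the growth factor Igf1 of 0.17 ± 0.14 (adjusted p = 0.311).

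Interferon response genes (13 genes; median -0.25; adjusted p = 0.177) did not pass as a list, with 2 members lower over all genes tested, Psmb8 and the surface antigen Ly6e (-0.46 ± 0.10, adjusted p = 0.0469, n = 3), and 4 lower adjusted over the list alone. The call of Ly6e was lost without T2 (adjusted p = 0.227), without T3 (0.273) and after median centring (0.0629). Neutrophil markers (12 genes; median 0.02; adjusted p = 0.356) had 0 members past either threshold and differed between pairs, with medians of 0.50 on T1, -0.34 on T2 and -0.11 on T3. The integrin Itgam had 0.33 ± 0.42 and the collagenase Mmp8 0.22 ± 0.33. Cell cycle genes (38 genes; median -0.10; adjusted p = 0.409) also had 0 members past either threshold and 30 of 38 gene means below 0, while the 2 of smallest p were above 0, the mitotic kinase Bub1 at 0.63 ± 0.43 and the centromere histone Cenpa at 0.41 ± 0.15. Glycolysis genes (7 genes; median -0.13; adjusted p = 0.686) had 0, with Tpi1 at -0.26 ± 0.27 and Pgk1 at -0.21 ± 0.30. Endothelial markers (5 genes; adjusted p = 0.761) had 0, with Sox17 at 0.30 ± 0.05 and Kdr at -0.25 ± 0.26. Megakaryocyte and platelet markers (7 genes; adjusted p = 0.959) had 0 over all genes tested, and the platelet integrin Itga2b was lower adjusted over the list alone (-0.44 ± 0.19), with Thbs1 at 0.29 ± 0.41. Camera placed the endothelial and megakaryocyte lists on the higher side, while their medians were -0.03 and -0.10 and their means -0.01 and -0.04.

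The 3 pairs moved together to different degrees. Across the 6039 tested spots, which are not independent replicates, Pearson's r was 0.42 between T1 and T2, 0.49 between T1 and T3 and 0.73 between T2 and T3, and Spearman's rho was 0.41, 0.43 and 0.66. The sign was shared by 66.8%, 66.4% and 74.2% of spots in these pairs of arrays, and 53.8% of spots had 1 sign on all 3 arrays, against 25% by chance.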

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

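Keeping the control spots (172 changed spots) and testing named spots alone (243) were added after the results were seen, and the other alternatives were planned. The numbers of changed spots, in total, higher and lower, were 171, 68 and 103 as reported. They were 0, 0 and 0 with the sign of T2 turned, with T1 turned and with T3 turned (20, 226 and 10 spots at an unadjusted p under 0.05 by limma). They were 1309, 785 and 524 with a dye term, 57, 4 and 53 with median centring, 816, 595 and 221 with centring and scaling, and 1165, 724 and 441 at a threshold of 0.10. Leaving out 1 array gave from 38 to 1095 changed spots, from 0 to 682 higher and from 38 to 413 lower, and from 8 to 10 lists. The cause of these differences was not tested. All 171 spots were among those called without T1, with the dye term and with scaling. Values on at least 2 arrays (233) and robust eBayes (150) stayed within 1.5 times of the total. With 1 value per gene 170 of 3462 genes passed, a count of genes and not of spots, and 98 of these genes had a changed spot. Lists passing numbered 9 as reported, 5 with T2 turned (of the 9, the ribosomal proteins alone), 6 with the dye term, 0 with an estimated correlation and 0 with directional fry (2 at an unadjusted p under 0.05), and the same 9 with either scaling. Of the results that passed as reported, 8 changed sign, each with T2 turned, and none of them passed in the opposite direction. The erythroid mean was -0.012, that of muscle 0.15 and that of the early-response list -0.15 (camera adjusted p = 0.892, 0.0576 and 0.279). The spots of Stxbp6, Hsd3b2, Nlgn1, Cc2d2b and Ly6g6c were at -0.18, -0.098, -0.20, -0.030 and -0.0030. Of 60 list genes named, sign changes of genes that did not pass over all genes tested numbered 21 with T2 turned, 2 without T2 (Col1a1 and Esr1) and 1 with centring and scaling, and with T1 or T3 turned the changed spots alone were counted. With 4 sign patterns of the 3 arrays no share under 0.05 can be reached: 1 of the 4 gave as many as 171 changed spots, and the highest of the others gave 0. Signal over background was not analysed here, so its limit on single spots is unknown.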

Other observations

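Chosen after the results were seen were the random lists, the use of Ms4a1, the count of the lowest array, the shares of spots with no single named gene, the random draws of blocks, the set of spots shared by the alternatives and the genes named outside the lists. The share of higher spots in a single block was set before its result was seen, and the calls and alternatives these tests use were planned.

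Genes outside the B-lineage list that were lower at gene level included Siglecg, an inhibitory receptor of B cells, which fell by 1.61 ± 0.06 on the log2 scale (3.04-fold, limma adjusted p = 0.000206, n = 3). Lower were also the transcription factors Foxo1 (-1.22 ± 0.19, adjusted p = 0.00127), Tcf3 (-1.03 ± 0.23, adjusted p = 0.00333) and Foxp1 (-0.96 ± 0.18, adjusted p = 0.00333), H2-Ob, a class II chaperone subunit (-0.95 ± 0.08), the GTPase Rhoh (-1.16 ± 0.31), the sialyltransferase St6gal1 (-1.09 ± 0.27) and the scaffold Bank1 (-0.51 ± 0.02, adjusted p = 0.0402). These are examples, picked from the changed genes and not tested as a group. Past the threshold as reported and under each of 8 alternatives that keep the signs and the threshold were 37 spots, all of them lower, which included 30 named genes, 6 of them in the B-lineage list. One of these alternatives, leaving out T3, called only 38 spots, all of them lower, which by itself was enough to keep higher spots out of this set. Others also left few higher spots, 4 after median centring and 21 without T2, against 68 as reported.

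Higher genes outside the lists included Dgat1, an enzyme of triglyceride synthesis, at 0.55 ± 0.02 (1.46-fold, limma adjusted p = 0.0277, n = 3). Another was Prom1, a surface protein of stem and progenitor cells, at 0.60 ± 0.21 (limma adjusted p = 0.0405). Without T3, 0 spots passed as higher, so the spots of Dgat1 and Prom1 did not pass there. Of 9 genes with more than 1 changed spot, 0 had changed spots in both directions, but 4 of 28 changed genes with more than 1 tested spot had spots of both signs. Among these, Traf6 had spots at -0.52, -0.54 and 1.30. Spots of 1 gene are not independent, so the shared direction in the 9 genes is no separate support for their calls. Of 4 control-type spots with the symbol ACT1, 1 stood at 1.14 on T1, 1.61 on T2 and 1.43 on T3, 1 at 1.04, -1.08 and 0.77, and the others had means of 0.15 and -0.025. The first of these had a mean of 1.39, and with the control spots kept 69 spots passed as higher, against 68.

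The 7 of 15 B-lineage genes that passed were lower on all 3 arrays, while the medians of all 15 were -0.66 on T1, -0.88 on T2 and -0.46 on T3. The list's mean was -0.97. The range that held 95% of the means of 10000 random lists was -0.21 to 0.097, and the lowest of them was -0.46. This comparison was chosen after the drop was seen and takes no account of dye orientation, so it does not decide on a dye bias. With the sign of T2 as deposited, a dye bias alone would give T2, of opposite dyes, the opposite sign to T1 and T3. The 3 medians above argue against that, and the list's call was kept with a dye term. With T2 read as Cy5 to Cy3, a dye bias that B-lineage genes share stays open. An equal loss of B cells of every stage stays open. Ms4a1, a marker of later B cells, had a mean of -0.25 (95% interval -0.58 to 0.087). The changed genes, selected for passing, had a median of -2.07, while the median of all 15 was -0.36. The 8 members that did not pass ran from -0.36 (Hhex) to 0.14 (Jchain), with Cd24a and Cxcr5 at 0.09. Without spot brightness the spots of these members cannot be judged. A lower share of B-cell precursors under testosterone may account for the drop of the 7 genes that passed, as may lower expression per cell. These were not tested against each other. If T2 was deposited as Cy5 to Cy3, the list's mean would be -0.21.

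The early-response list, with Fos, Dusp1 and Junb among its members, stood higher on T2 (median 0.98) and T3 (0.79) than on T1 (-0.05). T1 was the lowest array in 12 of its 15 genes, but with 1 array per pair, and with genes that share a sample, this count describes the pattern and decides nothing about a treatment effect of equal size in all 3 mouse pairs, which stays open. Differences between pairs in the time from death to freezing could give such a pattern and were not tested, since nothing in the labels records them.

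Of the 68 higher spots 63.2% had no single named gene, against 14.6% of the lower and 24.6% of all tested spots, and whether the rise belongs to sequences outside single annotated genes was not tested on other data. Position on the array stays open. The fullest block held 11 of the 68 (16.2%), where an even spread gives 3.13% (permutation p = 0.0003 over 10000 random draws). Of 32 blocks 24 held any, where random draws gave a median of 28. The draws took spots as independent, which spots of 1 gene, such as both of Angptl1 in the fullest block, are not. The permutation p may therefore overstate the clustering. The bound set beforehand, that no block would hold over 25%, was met but lies too far above the even share to exclude position, and 57 of the 68 lay outside that block. Named spots lay in the fullest block too, those of Bdp1, Cdh1, Ascc3 and Csgalnact1 and both of Angptl1. That block therefore does not by itself account for the share of spots with no single named gene. The wider spread of T2 stays open too: without T2, 10 of 21 higher spots (47.6%, exact 95% interval 25.7% to 70.2%) had no single named gene, an interval that takes the spots as independent and begins close to the 24.6% of all tested spots. The ratio on T2 was above that on T3 and that on T3 above that on T1 in 45 of the 68. Of all tested spots, whatever their sign, 21.2% had this order. The 68 were selected for high means and T2 had the widest spread, which favours this order, so these figures do not compare like with like.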
